A study of Homo sapiens with 4 samples.

How the data were processed

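The study measured total RNA from a colon cancer epithelial cell line, LSTGFBR2, that carries a doxycycline-inducible TGFBR2 construct. The 4 samples fall into 2 groups of 2, untreated cells and cells given TGF-β1, and each sample's group was taken from its title. RNA was hybridised as biotin-labelled cRNA to a 1-colour oligonucleotide array (HG-U133 Plus 2.0), on which a group of short probes, a probe set, reads each transcript.

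The deposited table holds 1 value per probe set and array. Per the series' design text, the authors made it by RMA, that is, background correction, quantile normalization of the probes and summarization per probe set. The submitters' processing notes also name RMA, and its software version is not given in the sources used here. The deposited values are on the log2 scale as judged from their range, which ran from 2.48 to 15.34 with array medians between 6.57 and 6.61. RMA pulls the arrays to a common distribution, so a shift of most transcripts in one direction cannot be seen in these values. It gives no detection call, so no probe set was called absent, and 2664 genes had a mean log2 value under 5, where changes are compressed.

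The table has 54675 probe sets, 62 of them array controls. Gene names came from the platform annotation given with the table. It pairs 41097 probe sets with 1 gene symbol and 1801 with several, and the other 11777 are not named here. Symbols were updated through the Entrez gene ID for 41043 of the 41097 probe sets, and the others kept the annotation's name. For the 10523 genes with several probe sets, the probe set with the highest mean over the 4 arrays was used, which left 19775 genes. No table column was left without a sample.

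The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, two-sided). All 4 arrays entered the fit, with no covariate and no filter on dim probe sets. Log2 fold changes are TGF-β1 minus untreated. Standard errors are limma's moderated ones, with 6.13 degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 19775 genes. The rule that the series' design text gives for a response signature, an unadjusted limma p under 0.05 with a rise of 2-fold or more, was also applied, with its mirror for lower genes. An exact permutation test of 2 arrays against 2 has 6 splits and cannot go below a two-sided p of 0.333, so none was used. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Part of that spread was shared by arrays of the same replicate number (deviations from the group means correlated at 0.364 across genes). The main fit does not remove it. The number of arrays limits the precision.

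The test, its thresholds, the choice of probe set, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. There were 20 lists of pathway and cell state genes and 3 lists of markers of other cell types (fibroblast, endothelial and leukocyte), with 629 of their 674 distinct genes measured here. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 23 lists, and again with the correlation estimated from the data. The genes named in the text are TGFBR2, the 12 with the highest and the 12 with the lowest log2 fold change among called genes whose groups did not overlap, and for each list up to 4 called members with the largest change. Where fewer than 2 members of a list were called, the 2 with the largest change are given as values. Any other gene in the Results is named there as chosen after its values were seen. Genes outside this rule in the closing observations, from the added lists or from the comparison of replicate numbers, were likewise chosen after their values were seen.

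Alternatives were a minimum mean log2 value of 5 or 7, an intensity trend in eBayes, centring of each array on its median or on 8 housekeeping genes, averaging the probe sets of a gene, testing every probe set, a replicate block, leaving out each array in turn, a further 2-fold minimum, unadjusted p-values, limma's treat against a fold of 1.2, and fry in place of camera. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes as camera does. The gene-level fit was tested on simulated data with the residual spread of these arrays, in which 200 of 19775 genes were changed. At adjusted p under 0.05 it recovered 2% of 50 genes changed 1.5-fold, 48% of 50 changed 2-fold, 84% of 50 changed 4-fold and 90% of 50 changed 8-fold, with 0 false calls. The simulated arrays were independent, without the spread that arrays of the same replicate number shared in the data. These rates therefore need not hold for the data. A simulated list of 30 genes shifted by 0.5 log2 had an adjusted p of 2.35e-34 with the preset correlation and 0.135 with the estimated one, and 0 of 20 unchanged lists were called. In this simulation the setting with an estimated correlation thus missed a shift of that size, although the genes were drawn independently. In the data, the actin list had an estimated correlation of -0.00503, under the preset 0.01. Its unadjusted camera p still went from 7.99e-13 to 0.0141. A larger p with the estimate is therefore not by itself a sign of correlated genes. Other lists gave estimates of up to 0.294 (interferon-stimulated genes). The simulation, with independent genes, does not show how the preset correlation behaves where the genes of a list move together.

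The labels leave the doxycycline treatment of the untreated arrays open. The series' design text speaks of cells seeded with or without doxycycline, and does not say which arrays those were. The treatment protocol gives doxycycline at 1 µg/ml from seeding, where the growth protocol gives 1 µM, and the difference is not resolved here. It also gives TGF-β1 at 5 ng/ml added 16 hours later, and a further 16 hours of culture. Cells were plated at 60% confluence, per the design text. The untreated arrays are labelled only as having no treatment.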

Results

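Gene expression of colon cancer epithelial cells with and without TGF-β1, a cytokine that restrains epithelial growth, was measured on 4 arrays. LSTGFBR2 cells carry the type II TGF-β receptor under a doxycycline-inducible promoter. Of the 4 arrays, 2 came from untreated cells and 2 from cells given 5 ng/ml TGF-β1 for 16 hours. Expression was read for 19775 genes as RMA values on the log2 scale. Across genes, the replicate arrays correlated at r = 0.996 in both groups, and arrays of different groups at 0.990 to 0.992. Between replicates, 59 genes differed by 2-fold or more in the untreated group and 62 in the TGF-β1 group, against 285 to 428 between groups.

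The receptor carried by the construct was examined first, because it bears on what the arrays compare. TGFBR2 was 39.9-fold higher in the TGF-β1 arrays by the _s_at one of its 2 probe sets, the brighter on average and the one used for the gene, which was the largest change among all genes. It read 9.44 and 9.55 in the untreated arrays and 14.70 and 14.92 in the TGF-β1 arrays, close to the highest values of the arrays (15.26 to 15.34). The log2 fold change was 5.32 ± 0.118 (SE, n = 2 per group, limma adjusted p = 0.000114). The other TGFBR2 probe set, the _at one, read 10.6 ± 0.235 (SD, n = 2) in untreated and 10.7 ± 0.124 in TGF-β1 arrays, a log2 fold change of 0.03 ± 0.148 (SE, limma adjusted p = 0.980 over all probe sets). In the untreated arrays the _at one was thus the brighter. The _s_at one was used for the gene through its level in the TGF-β1 arrays, and the rank of TGFBR2 among all genes rests on that choice. The mean of both probe sets gave a log2 fold change of 2.67. The labels do not say which arrays received doxycycline, so the groups compared below differ in the signal of 1 TGFBR2 probe set as well as in TGF-β1.

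**Figure D1:**
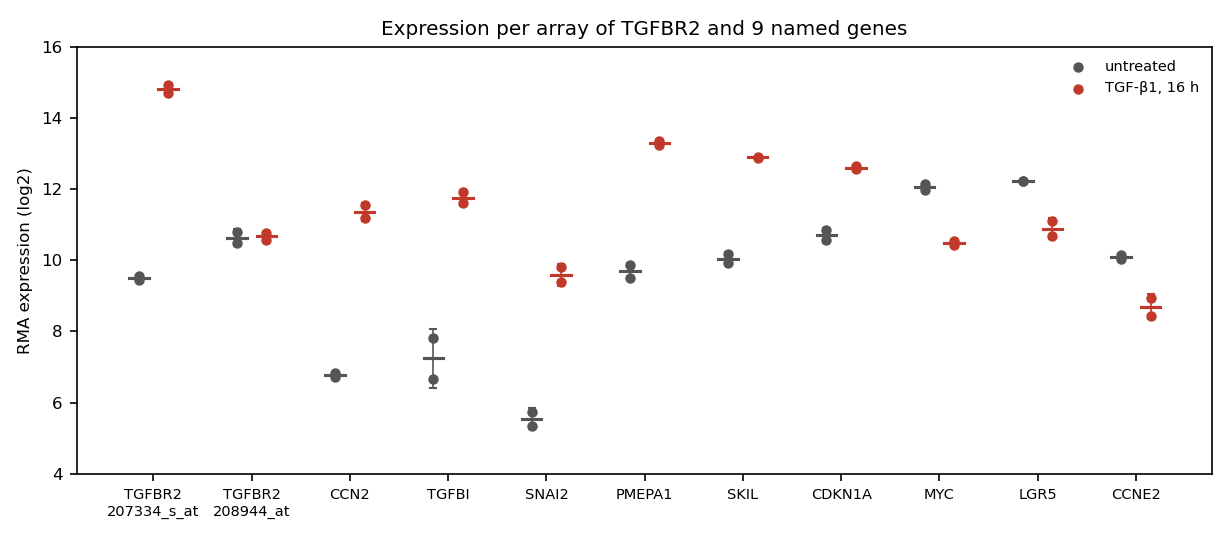
RMA expression (log2, vertical axis) of TGFBR2 by each of its 2 probe sets and of 9 other named genes (horizontal axis); points are single arrays, horizontal lines group means and error bars SD (n = 2 per group). The _s_at probe set of TGFBR2 lies at 9.44 and 9.55 in untreated and 14.70 and 14.92 in TGF-β1 arrays, while the _at probe set overlaps between the groups.

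The study's design text uses this comparison for a TGF-β response signature. As the groups also differ in TGFBR2 signal and their doxycycline treatment is not given, the changes are described here as those between the 2 groups of arrays. At limma adjusted p under 0.05, 369 genes rose and 291 fell, 660 in all. With the replicate block 561 genes were called, 441 of them among the 660. By the study's own signature rule, 201 genes were at least 2-fold higher, and the mirror rule gave 73 genes that were lower. Of these, 172 and 62 also passed the adjusted threshold. After TGFBR2, CCN2, which encodes connective tissue growth factor, rose 24.1-fold, from 6.78 ± 0.090 to 11.4 ± 0.253 (SD, n = 2, limma adjusted p = 0.00049). TGFBI, a secreted matrix protein named for its induction by TGF-β, rose 22.8-fold, from 7.24 ± 0.831 to 11.8 ± 0.219 (SD, n = 2). SNAI2, the transcription factor Slug, rose 16.7-fold, the transcriptional repressor BHLHE40 12.4-fold, the metalloproteinase gene MMP10 12.3-fold and PMEPA1, an inhibitor of SMAD signalling, 12.2-fold. Rises of 7.21-fold to 8.29-fold were seen for ITGA2 (integrin α2), S100A3 (a calcium-binding protein), EDN1 (endothelin-1), NEDD9 (a focal adhesion scaffold) and SKIL (a SMAD corepressor). The falls were smaller. CYTIP fell by 2.20 ± 0.214 on the log2 scale (SE) and PCK1, which encodes a gluconeogenic enzyme, fell by 2.14 ± 0.347. The transcription factor genes MYB and MYC were 3.11-fold and 2.98-fold lower, MYC going from 12.1 ± 0.103 to 10.5 ± 0.095 (SD, n = 2, limma adjusted p = 0.00311). TMEM80, CALB1 (calbindin), EMSLR, CCNE2 (cyclin E2), LYAR (a nucleolar protein), FAM222A-AS1, NCR3LG1 (a natural killer cell receptor ligand) and HLF (a transcription factor) were 2.55-fold to 2.90-fold lower. In place of 660 genes, 70 were called without untreated replicate 1, 93 without untreated replicate 2 and 104 without either TGF-β1 replicate, since only 1 residual degree of freedom is left. The untreated levels of SNAI2 (5.54) and MMP10 (5.08) and the TGF-β1 levels of CYTIP (5.81), CALB1 (6.06), FAM222A-AS1 (6.15) and HLF (6.54) lay under the array medians. The medians over the tested genes alone were higher, 7.64 to 7.67. Under these lay also the untreated levels of CCN2 (6.78), TGFBI (7.24) and S100A3 (6.59) and the TGF-β1 level of EMSLR (6.68). RMA values do not show whether such levels were above background, so the sizes of these changes are less certain. Of the 12 highest genes 10 passed with each array left out, all but MMP10 and S100A3, and of the 12 lowest 2 did, MYC and NCR3LG1.

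**Figure D2:**
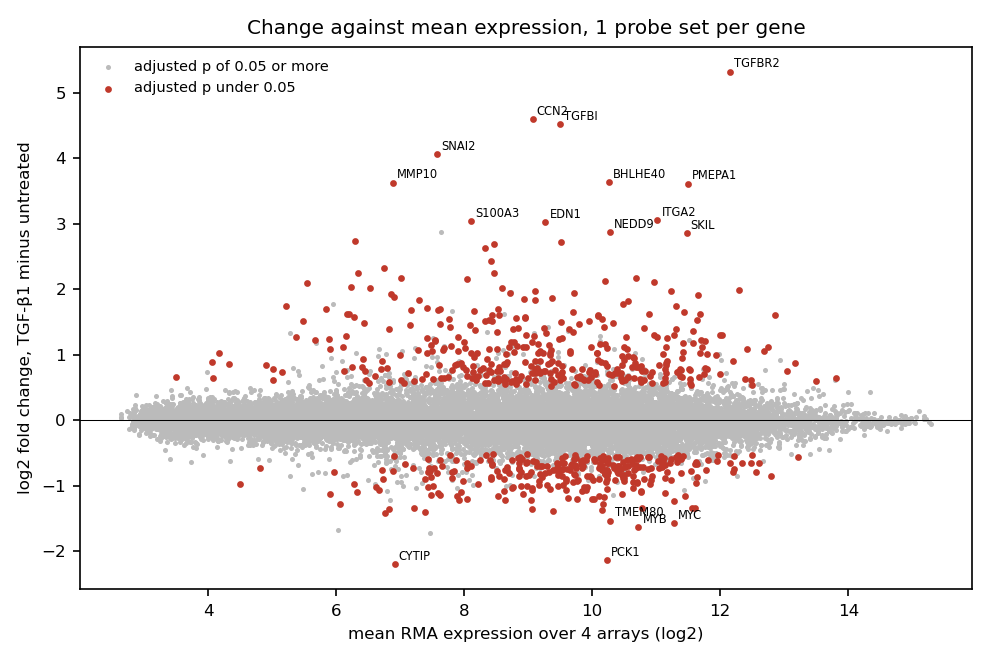
Log2 fold change, TGF-β1 minus untreated (vertical axis), against mean RMA expression over the 4 arrays (log2, horizontal axis), with 1 point per gene (19775 genes). The 660 genes at limma adjusted p under 0.05 are red, and the highest 12 and the 5 lowest of the named genes are labelled.

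Direct SMAD targets and feedback regulators of the TGF-β pathway were examined as a list. Of 28 measured members, 15 rose, 0 fell and 13 did not pass, with a median log2 fold change of 0.83. CCN2, TGFBI, SNAI2 and BHLHE40 led the list. The count was 19 higher and 1 lower when adjusted over the list alone. Camera placed the list above other genes (adjusted p = 1.21e-18, and adjusted p = 0.204 with an estimated correlation). With any 1 of the 4 arrays left out, 9 to 11 members rose. Of 24 measured receptors, ligands and SMADs, 4 rose and 0 fell. Besides TGFBR2 these were the type II BMP receptor gene BMPR2 (2.81-fold), SMAD3 (1.87-fold) and the type I receptor gene ACVR1 (1.66-fold), and 2 members rose with any 1 array left out. Adjusted over the list alone, 4 were higher and 4 lower, and the list as a whole did not stand apart from other genes (camera adjusted p = 0.388). Among 15 ID and BMP-response genes, 1 rose, HES1 (log2 fold change 0.78 ± 0.143 SE), which did not pass in any of the 4 fits with 1 array left out (limma adjusted p from 0.0902 to 0.250), and 4 were higher and 1 lower adjusted over the list alone. MSX2 and ID1, at log2 fold changes of 1.05 and 0.92, did not pass (limma adjusted p = 0.0620 and 0.0632), though MSX2 passed without TGF-β1 replicate 2 (0.0392) and ID1 without TGF-β1 replicate 1 (0.0499). Over genes with a mean log2 of 7 or more both passed (0.0463 and 0.0470), and ID1 did with an intensity trend (0.0476). The camera adjusted p was 0.689, with an upward direction although the median was -0.05.

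Some members of the actin and adhesion, matrix, mesenchymal and epithelial lists rose. Of 36 actin and focal adhesion genes, 8 rose, among them ITGA2, ITGB5 (integrin β5, 3.92-fold), PDLIM7 (an actin-associated PDZ and LIM domain protein, 3.61-fold) and the small GTPase gene RHOB (2.46-fold). Adjusted over the list alone, 16 were higher and 2 lower. The list median was 0.35 (camera adjusted p = 9.18e-12, and adjusted p = 0.204 with an estimated correlation). Of 51 extracellular matrix and remodelling genes, 4 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.13, camera adjusted p = 0.000677, and adjusted p = 0.255 with an estimated correlation). The 4 were MMP10, LAMB3 (laminin β3, 3.54-fold), PLAUR (the urokinase receptor, 2.84-fold) and P4HA2 (a collagen prolyl hydroxylase, 1.88-fold). The 1 that fell, COL4A2, is named after its values were seen (log2 fold change -0.53). In the mesenchymal transition list, 4 of 24 genes rose and 0 fell, the same 4 and 0 adjusted over the list alone. These were SNAI2, NT5E (the ecto-nucleotidase CD73, 3.82-fold), SPOCK1 (a proteoglycan, 2.43-fold, from an untreated level of 5.52 that also lay under the array medians) and MSN (moesin, 2.05-fold). The list median was 0.03 (camera adjusted p = 0.0365, and adjusted p = 0.384 with an estimated correlation), and the call was lost without untreated replicate 1 (0.0504) or TGF-β1 replicate 1 (0.107), and also with genes of mean log2 under 5 left out (0.0618) and over probe sets (0.0979). Members chosen after their values were seen, namely VIM (vimentin), CDH2 (N-cadherin), FN1 (fibronectin) and ZEB1, had log2 fold changes of -0.23, -0.01, 0.03 and 0.05, and none passed. Of 32 epithelial junction genes, 2 rose and 0 fell, JUP (plakoglobin, 2.02-fold) and CLDN4 (claudin 4, 1.90-fold), and 3 and 0 did adjusted over the list alone. This list also lay above other genes (median 0.10, camera adjusted p = 0.00575, and adjusted p = 0.352 with an estimated correlation), a call lost without TGF-β1 replicate 1 (0.0664). With any 1 of the 4 arrays left out, 3 or 4 of the actin genes, 1 to 3 of the matrix genes, 1 or 2 of the mesenchymal genes and 0 of the epithelial genes rose.

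Of 46 measured genes of the cell cycle and DNA replication, 12 fell, 0 rose and 34 did not pass (21 and 1 adjusted over the list alone, median -0.25). CCNE2 was 2.63-fold lower, CCNE1 (cyclin E1) 1.89-fold, the replication factor gene MCM10 1.80-fold and the transcription factor gene E2F2 1.77-fold. Camera gave an adjusted p of 7.12e-07, and adjusted p = 0.398 with an estimated correlation. With any 1 array left out, 0 or 1 members fell. Among 23 growth arrest regulators, 4 rose and 4 fell (7 and 6 adjusted over the list alone). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 3.75-fold, from 10.7 ± 0.203 to 12.6 ± 0.070 (SD, n = 2, limma adjusted p = 0.00261). BTG1, an antiproliferative gene, rose 2.88-fold and GADD45B, a stress-response gene, 2.11-fold, while MYC fell. The others called, chosen after their values were seen, were NDRG1 (1.62-fold higher), the phosphatase gene CDC25A (1.77-fold lower), the kinase gene CDK4 (1.68-fold lower) and E2F5 (1.57-fold lower). The list as a whole had no direction (median -0.04, camera upward with adjusted p = 0.898). With any 1 array left out, 2 or 3 members rose and 1 fell. Of 27 apoptosis regulators, 1 rose, GADD45B, and 0 fell, and 4 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.514, and 0.0222 over probe sets). With 1 array left out, GADD45B passed only without TGF-β1 replicate 1 (limma adjusted p from 0.0455 to 0.188 over the 4 fits). TNFSF10, the TRAIL ligand, had a log2 fold change of 1.01 and did not pass (limma adjusted p = 0.0548).

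Intestinal stem cell genes were among those that fell. Of 27 Wnt target and stem cell genes, 5 fell and 2 rose (9 and 3 adjusted over the list alone). LGR5, a marker of intestinal stem cells, was 2.53-fold lower, going from 12.2 ± 0.011 to 10.9 ± 0.295 (SD, n = 2, limma adjusted p = 0.0136). CDCA7 was 2.54-fold lower, and MYC belongs to this list too. Those that rose included NKD1, a Wnt feedback inhibitor (2.64-fold). The remaining called members, chosen after their values were seen, were the stem cell transcription factor gene ASCL2 (2.24-fold lower), EPHB3 (2.15-fold lower) and the Wnt antagonist gene DKK1 (2.16-fold higher). The list did not pass as a whole (median -0.09, camera adjusted p = 0.0619), and passed over probe sets (0.0466) and over genes with a mean log2 of 7 or more (0.0485). With any 1 array left out, 1 to 5 members fell and 0 or 1 rose. Of 34 absorptive lineage genes, 1 rose, the receptor kinase gene EPHA2 (1.97-fold), and 1 fell, the intestinal transcription factor gene CDX2 (1.66-fold), as also adjusted over the list alone, and 0 passed with any 1 array left out (camera adjusted p = 0.360). None of 38 secretory lineage genes passed by limma, over all genes or adjusted over the list alone, and 9 were lower and 0 higher at an unadjusted p under 0.05. INSM1 and MUC6 had the largest log2 fold changes by the probe sets used, while their other probe sets read -0.27 and -0.10. INSM1 read 5.29 and 6.71 in untreated and 4.91 and 5.00 in TGF-β1 arrays, where only 6.71 lay above the array medians. The changes by the probe sets used were -1.05 ± 0.417 and -0.72 ± 0.474 (SE). With 1 array left out these were -1.76 to -0.34 for INSM1, which passed without untreated replicate 1 (limma adjusted p = 0.0384), and -1.50 to 0.064 for MUC6. Camera placed this list below other genes (median -0.10, adjusted p = 0.00885, and adjusted p = 0.384 with an estimated correlation), a call lost without untreated replicate 2 (0.0602), and 1 member fell without untreated replicate 1.

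**Figure D3:**
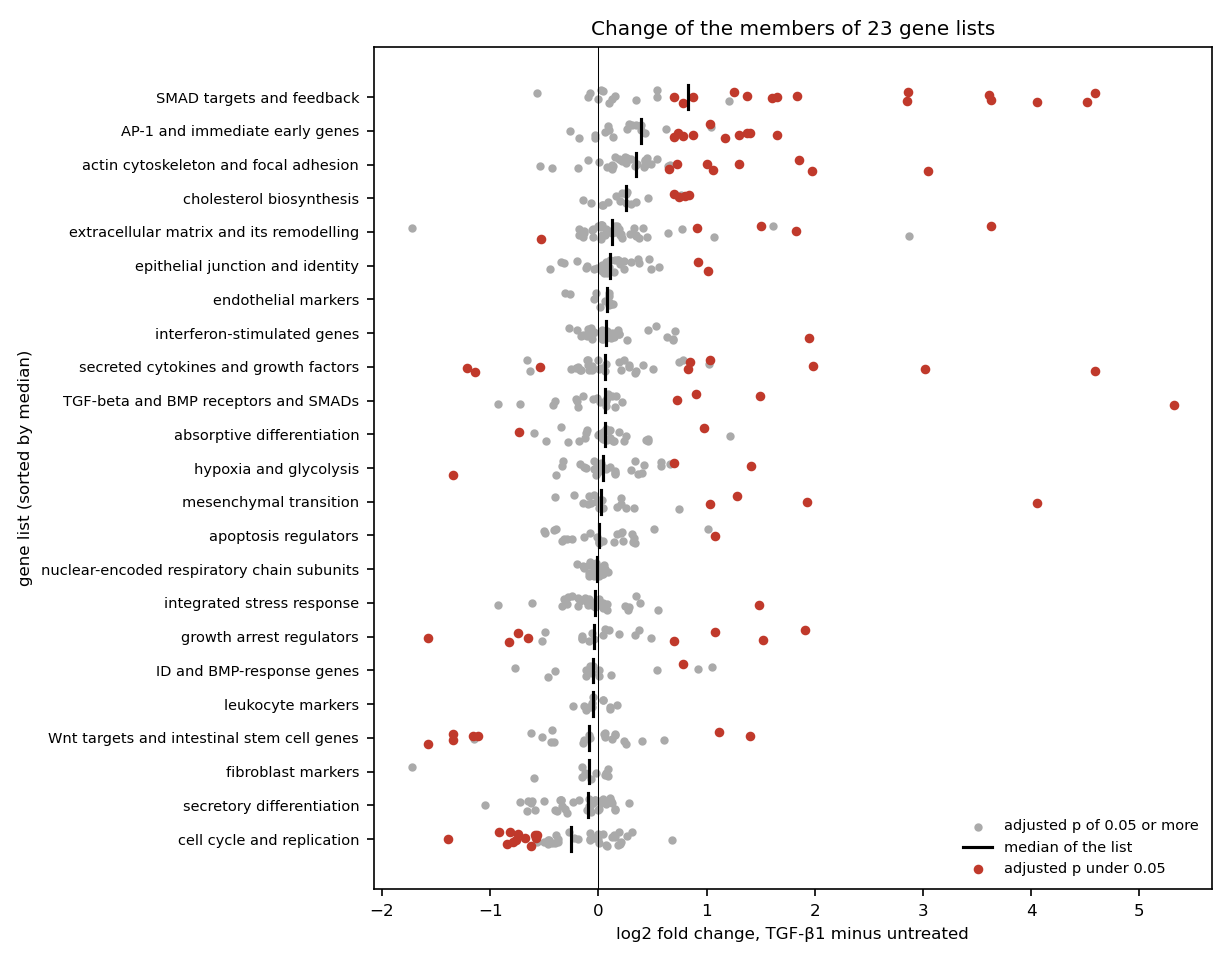
Log2 fold change, TGF-β1 minus untreated (horizontal axis), of each measured member of the 23 gene lists (vertical axis, sorted by median), with vertical spread within a list added only to separate points. Red points passed limma adjusted p under 0.05, grey points did not, and black lines mark medians, from -0.25 for cell cycle genes to 0.83 for SMAD targets.

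Signalling, metabolic and stress lists differed in how many members moved. Of 27 AP-1 and immediate early genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.39, camera adjusted p = 5.42e-10, and adjusted p = 0.222 with an estimated correlation). They included JUNB (3.13-fold), FOS (2.65-fold), JUN (2.47-fold) and CCN1 (2.60-fold), and 1 to 3 passed with any 1 array left out. Of 19 cholesterol synthesis genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.26, camera adjusted p = 5.46e-06, and adjusted p = 0.384 with an estimated correlation), and 0 passed with any 1 array left out. These were HMGCS1 (1.79-fold), MSMO1 (1.74-fold), STARD4 (1.67-fold) and IDI1 (1.62-fold). Among 39 secreted factor genes, 6 rose and 3 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.0748, 0.0143 without TGF-β1 replicate 2, 0.0288 over genes with a mean log2 of 7 or more, 0.0478 with arrays centred on their medians and 0.000866 over probe sets). EDN1, CCN2 and the Notch ligand gene JAG1 (3.94-fold) rose, and the chemokine gene CXCL2 was 2.32-fold lower. The related CXCL3 and CXCL1, chosen after their values were seen, were 2.20-fold and 1.46-fold lower. With any 1 array left out, 3 rose and 0 or 1 fell. Of 31 hypoxia and glycolysis genes, 2 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0870, 0.0371 with averaged probe sets, 0.0232 without untreated replicate 1 and 0.0322 without TGF-β1 replicate 2). The glucose transporter gene SLC2A1 rose 2.66-fold and NDRG1 1.62-fold, while the hexokinase gene HK2 was 2.54-fold lower. With 1 array left out, 0 or 1 members rose and 0 or 1 fell. Among 36 interferon-stimulated genes, 1 rose, OASL (3.86-fold), and 0 fell, also adjusted over the list alone. SAMD9 was next at a log2 fold change of 0.71 and did not pass (limma adjusted p = 0.111), and the list's camera adjusted p was 0.0606. The list median was 0.14 without untreated replicate 1, 0.18 without TGF-β1 replicate 2 and -0.064, with the camera direction turned, without untreated replicate 2. Of the 36 genes, 26 were higher in replicate 1 than in replicate 2 in both groups and 7 lower. Leaving out 1 array therefore mixes that difference with TGF-β1, and these medians do not speak for a TGF-β1 effect. With all arrays kept the camera adjusted p was 0.0376 with averaged probe sets, 0.000901 over probe sets and 0.0440 with arrays centred on their medians. With the replicate block it was 0.0166, and SAMD9 passed (limma adjusted p = 0.0422). Of 31 integrated stress response genes, 1 rose, DDIT4, an inhibitor of mTOR signalling (2.79-fold), and 0 fell, against 1 and 1 adjusted over the list alone. GDF15 had a log2 fold change of -0.92 and did not pass (limma adjusted p = 0.0650), and the list median was -0.03 (camera adjusted p = 0.725). None of 28 respiratory chain genes, each by its brightest probe set, passed by limma, over all genes, adjusted over the list alone or at an unadjusted p under 0.05. The largest log2 fold changes among them were -0.19 for ATP5MC1 and -0.14 for CYCS (list median -0.01, camera adjusted p = 0.689). The other probe sets of CYCS (cytochrome c) read -0.80 and -0.98, and averaged over its 3 probe sets the gene passed (-0.64, limma adjusted p = 0.0281).

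No marker of another cell type passed in the main limma fit, over all genes or adjusted over each list alone. At an unadjusted p under 0.05, 2 fibroblast markers and 1 endothelial marker were lower, and 0 leukocyte markers passed. The 12 fibroblast markers had a mean level of 5.68 in untreated and 5.46 in TGF-β1 arrays (camera adjusted p = 0.283), the 12 endothelial markers 5.94 and 5.95 (0.803), and the 12 leukocyte markers 6.16 and 6.14 (0.821). COL3A1 and LUM had the largest log2 fold changes of the fibroblast markers, -1.72 ± 0.663 and -0.60 ± 0.150 (SE), and COL3A1 was higher in replicate 1 than in replicate 2 by 1.70 log2 in the untreated and 1.54 in the TGF-β1 arrays. LUM was dim, at 3.71 in untreated and 3.11 in TGF-β1 arrays, and its other probe set changed by -6.01e-05. The largest log2 fold changes of the endothelial markers were those of ERG and TIE1, at -0.30 and -0.27, and of the leukocyte markers those of LAPTM5 and CD3D, at -0.23 and 0.17. With the replicate block COL3A1 passed (limma adjusted p = 0.0180). As a measure of RNA quality, the 3′ minus 5′ difference of the ACTB control probe sets was 0.37 and 0.34 log2 in the untreated and 0.21 and 0.26 in the TGF-β1 arrays, and for GAPDH -0.15 and -0.098 against -0.11 and -0.094. Another probe set of the same gene had a log2 fold change of opposite sign for NEDD9 (lowest -0.03), BMPR2 (-0.12), MSX2 (-0.01), CLDN4 (-0.07), P4HA2 (-0.01), PDLIM7 (-0.03), IDI1 (-0.25), CXCL2 (0.17), ERG (0.05) and LAPTM5 (0.21). Some of these probe sets were dim, with untreated means of 3.69 for MSX2, 3.91 for P4HA2 and 4.16 for CXCL2. The sign was shared by 3 of 4 other probe sets for NEDD9, 4 of 5 for BMPR2 and 5 of 6 for PDLIM7. It was shared by 1 of 3 for IDI1 and 0 of 1 for CLDN4 and for LAPTM5. Where the sign was shared, other probe sets could still differ in size from the one used (in brackets). Examples were CCNE1 at -0.10 (-0.92), E2F2 at -0.33 to -0.26 (-0.82), HES1 at 0.076 to 0.64 (0.78) and MYB at -0.26 (-1.64). Among the 12 highest genes, BHLHE40 read 2.21 (3.63), EDN1 0.25 to 2.02 (3.02) and SKIL 0.84 to 3.61 (2.85). Averaged over all probe sets of a gene, the calls of HES1, CLDN4, P4HA2, GADD45B, CXCL2 and IDI1 were lost (limma adjusted p from 0.0535 to 0.230), and that of CYCS was gained.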

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

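Among the 13522 probe sets that carry no single gene name, and so enter no gene of the report (they were tested only where every probe set was a feature), 41 were higher and 22 lower in the TGF-β1 arrays at limma adjusted p under 0.05 over all probe sets, that is 0.303% and 0.163%. The largest log2 fold changes among them were 3.33 and -1.76. Of the probe sets with 1 gene name, 1.11% passed in the same fit. They stand here because they differ from the untreated arrays in data the comparisons do not use, and no explanation was tested.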

How the results depend on the processing

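The total of 660 called genes became 234 with a 2-fold minimum (172 higher, 62 lower), 212 under treat (153 and 59) and 3305 at unadjusted p under 0.05 (1617 and 1688). With 1 array left out it was 70 to 104, with 64 to 85 higher and 6 to 21 lower genes, as fewer arrays leave less residual information. Lower genes numbered 443 with a minimum mean log2 of 7, where fewer genes were tested, and 166 with every probe set tested, where more were. Testing every probe set also gave 394 signature features and 125 in the mirror, in place of 201 and 73 genes. That setting counts genes several times and adds the probe sets without a single gene name, and the share of each was not tested. Without 1 array the mirror count was 65 to 118, with 115 without untreated replicate 2 and 118 without TGF-β1 replicate 1, and the cause was not tested. The number of lists called fell from 9 to 0 with an estimated correlation, also for lists whose estimate was under the preset 0.01. Fry, which tests a list against no change and not against other genes, called 5, among them 4 of the 9 and the receptors and SMADs (adjusted p = 0.0329), and a list it did not call has not thereby lost its camera call. The receptor and SMAD list holds TGFBR2 itself (log2 fold change 5.32), against a list median of 0.065. The list without TGFBR2 was not tested. With 1 array left out the number of camera calls was 7 to 12, and it was 12 over probe sets and 11 with averaged probe sets, with array medians or with a minimum of 7. Over the 12 settings that kept the preset correlation, the camera adjusted p ran from 0.00215 to 0.0664 for epithelial, 0.00515 to 0.107 for mesenchymal, 0.000876 to 0.0602 for secretory, 0.0466 to 0.179 for Wnt and stem cell, 0.000866 to 0.227 for secreted factor, 0.0222 to 0.819 for apoptosis, 0.0232 to 0.527 for hypoxia and 5.05e-05 to 0.931 for interferon-stimulated genes. A minimum mean log2 of 7 and an intensity trend added TNFSF10 (0.0412 and 0.0487) and GDF15 (0.0480 and 0.0497). Arrays with the same replicate number share only a number in the labels. Their deviations from the group means correlated at 0.364 across genes, and the fit with the replicate block called 561 genes, 441 of them among the 660. It ended the calls of LYAR, SMAD3, HES1, E2F2, GADD45B and IDI1, added TNFSF10, GDF15, SAMD9, COL3A1 and the interferon-stimulated list (adjusted p = 0.0166), and changed no other call of a named gene or list. The camera direction of some uncalled lists turned, and the cause was not tested. For the growth arrest list this happened with a minimum of 7 (median -0.063), over probe sets (-0.044) and without untreated replicate 2, and its median was -0.078 to -0.0064 with 1 array left out. Such medians were -0.14 to 0.090 for the stress response (-0.030 under fry, where the direction turned), -0.054 to 0.028 for respiratory chain, -0.064 to 0.18 for interferon-stimulated and -0.089 to -0.0054 for leukocyte genes. Turned directions also came with medians of 0.020 for endothelial markers over probe sets, and of 0.0087 (averaged probe sets) and 0.014 (every probe set) for leukocyte markers. The log2 fold changes of MUC6 (-1.5 to 0.064) and of the _at probe set of TGFBR2 (-0.14 to 0.20) also changed sign with 1 array left out. Centring on array medians or housekeeping genes moved the median of all genes to -0.026 and -0.0083 log2. It turned the median of the apoptosis list (-0.016 with array medians) and the sign of no named gene. Array medians ended the call of P4HA2 (0.0503) and added the secreted factor (0.0478) and interferon-stimulated (0.0440) lists, and housekeeping genes added TNFSF10 (0.0460). RMA gives no background or detection values, so signal over background could not be judged.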

Other observations

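The ribosome biogenesis, purine synthesis, YAP, p53, Notch and EGFR lists of this part were written after the first fit had been seen and before their own tests, and hold no gene of the earlier lists. The tests on TGFBR2, doxycycline and the replicate numbers were chosen after the result was seen.

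Of 23 measured genes of ribosome biogenesis, 13 fell and 0 rose by limma, alongside the fall of MYC (21 and 0 adjusted over the list alone), and 23 of 23 had a negative log2 fold change. The ribosome assembly factor gene MRTO4 fell by 0.98 ± 0.130 on the log2 scale (SE), NOP16 by 0.96 ± 0.122 and POLR1B, a subunit of RNA polymerase I, by 0.95 ± 0.129. The list median was -0.66 (camera adjusted p = 1.22e-20 over the 6 added lists, and adjusted p = 0.400 with an estimated correlation), and -0.712 to -0.580 with 1 array left out. Of 12 purine and one-carbon synthesis genes, GART fell and all 12 had negative values, with 7 lower adjusted over the list alone and a median of -0.30 (camera adjusted p = 6.53e-06, and adjusted p = 0.400 with an estimated correlation). Since both lists are known MYC targets, a candidate explanation is that they followed the lower MYC transcript. Slower growth of the cells for another reason would lower them too, and these arrays do not separate these explanations.

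Other groups next to strongly changed genes showed no such shift by camera. The median log2 fold change was 0.14 for 16 YAP target genes other than CCN1 and CCN2 (camera adjusted p = 0.124), of which F3 rose, and 0.051 for 19 p53 targets other than CDKN1A (0.124), of which TP53INP1 rose. It was -0.022 for 17 Notch genes outside the earlier lists (0.343), of which JAG2 fell. JAG1 and HES1, both called higher, were in earlier lists and so are left out of this median. So are HEY1, DLL1 and DLL4, none of which was called. The median was 0.13 for 14 EGFR family and feedback genes outside the earlier lists (0.381), of which SPRY4 rose and SPRY1 fell. The ligand genes AREG, EREG, HBEGF and TGFA, in the secreted factor list, are left out of it. Without untreated replicate 2 the YAP list passed (0.0475). These tests leave open whether those pathways took part.

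The unequal change of the TGFBR2 probe sets argues against a rise of the cells' own transcript as both probe sets read it, because the _at probe set changed by 0.031 ± 0.148 log2 (SE). The lower of the fold changes of the _s_at probe set under 2 other scalings was 5.30 log2. Those scalings shift each array as a whole and move both probe sets alike. They could not have changed the difference between the probe sets and so do not test scaling as its source. Transcript of the inducible construct in the TGF-β1 arrays, and a form of the cells' own transcript that the _at probe set does not read, both stay open: the difference of 5.29 log2 between the probe sets is the pattern itself and tests neither, and probe positions and the construct's sequence were not analysed here. If doxycycline was given to the TGF-β1 arrays alone, its own effects and those of TGF-β1 cannot be told apart, since no array had doxycycline without TGF-β1, and the stress response list (median -0.03) does not settle it.

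Arrays that share a replicate number resembled each other in specific genes. Of the genes that differed by 2-fold or more between numbers 1 and 2 in both groups, 28 did so the same way in both groups and 1 in opposite ways. Independent lists would share 0.096 genes higher in number 1, where 22 were seen, and 0.015 higher in number 2, where 6 were seen. The interferon-stimulated genes IFI27 (12.7 and 9.62 in untreated, 12.6 and 9.99 in TGF-β1 arrays) and IFI6 were higher in number 1, as were TFF2, KRT20, CD55 and COL3A1, whereas OLFM4, LGALS1 and ASNS were higher in number 2. RNA degradation is argued against, as the 3′ minus 5′ control differences moved by at most 0.054 log2 between numbers. Among 36 interferon-stimulated genes, 26 were higher in number 1 in both groups, against 27.2% of all genes. A candidate explanation that stays open is a shared culture, passage or processing day for each number, which the labels do not state and which these counts, being the pattern itself, do not test.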
